A study of Mus musculus with 2 samples.

How the data were processed

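Single-cell RNA sequencing measured polyadenylated RNA in the corneal epithelium of male C57BL/6J mice aged 20 weeks. The 2 libraries were a control pool and a diabetic pool, each of 4 corneas from 2 mice. Diabetes had been induced with 1 injection of streptozotocin at 160 mg/kg. Streptozotocin is a toxin taken up by pancreatic beta cells, and the loss of insulin leaves the animal hyperglycaemic. Control mice had received the citrate buffer. Diabetic mice had kept a blood glucose above 250 mg/dL over the 12 weeks of the study, per the labels. The epithelium was lifted from the cornea enzymatically, dissociated with trypsin and loaded on the Chromium Next GEM 3′ v3.1 assay, per the labels' protocols. That assay captures each cell in a droplet and tags each captured molecule near its 3′ end with a unique molecular identifier (UMI), so that copies made by PCR are counted once.

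The deposited matrix holds whole UMI counts per gene and cell, not normalized, for 17492 genes and 17808 cells. A deposited cell table gives each cell's group and 1 of 8 cell type labels chosen by the authors (LSC, Basal, TAC1, TAC2, Wing, Squam, Conj and Immune). The meaning of the abbreviations, the way clusters were named and the filters on cells are not given in the sources used here. Cell Ranger 5.0.0, Seurat 4 and the mouse build mm10 are named in the submitters' processing notes, without their roles. The lowest UMI total of a cell was 520, the fewest genes in a cell was 253 and the highest mitochondrial share was 29.3%. Every gene in the matrix had a count in at least 1 cell, and 64 genes were seen in fewer than 3 cells.

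Counts were summed over the cells of a library, for all cells, for a basal class (cells labelled Basal or LSC), for a suprabasal class (Wing or Squam) and for each label. Sums were expressed as CPM, the count of a gene relative to the total count of the same sum. Each CPM has an exact 95% Poisson interval, each ratio of 2 CPM an exact conditional binomial interval, and each share of cells an exact 95% Clopper-Pearson interval. The limits of a ratio of 2 shares are quotients of opposite ends of the 2 share intervals, and are wider than a 95% interval. All of these cover counting error only. With 1 library per group there is no replicate, and cells of a pool are not replicates, so no test between groups was run and no p-value was computed. A gene was called higher or lower in the diabetic library by a fixed rule of size: a CPM ratio of 1.5 or more either way, 50 or more summed counts over both libraries, and Poisson intervals of the CPM that do not overlap. The rule describes these 2 libraries.

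Genes named in the text followed a rule fixed before the data were examined. In all cells and in each class, the 12 genes per direction with the largest log2 ratio after adding 10 CPM to both values were taken, among genes of 20 CPM or more in the higher library. Ribosomal protein genes, unnamed gene models, Xist and Y-linked genes were left out, a gene named for all cells had to go the same way in both classes, and a gene named for 1 class the same way in all cells, with no demand on the other class. Some genes that this rule takes are not reported here. For 33 gene lists, fixed at the same time, the median log2 ratio of the measured members was set against 10000 random lists matched over 20 bins of expression. Its percentile describes these libraries and is no test. A list was called outside the random range below percentile 2.5 or above 97.5. Up to 2 members per direction with the largest ratios are examples. A further 16 lists of cell type markers were summed.

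For the share of cycling cells, each cell was thinned at random to 5000 UMIs, and shallower cells were left out (486 control and 264 diabetic cells). A cell with 2 or more UMIs over the G2 and M phase list was counted. Doublets were scored with Scrublet. Its automatic threshold marked 0 cells in either library, so the alternative without doublets used the score of the cell that closes the top 8% of each library. Cells at or above that score, ties included, were left out (769 control and 706 diabetic cells). Cells were also clustered again by the Leiden method from 2000 variable genes and 30 components, with and without centring each gene within its library. Gene positions, GC content and transcript length came from GENCODE M21 on GRCm38, the assembly that mm10 names, and 98.9% of measured genes had a GC content and length. The tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0, leidenalg 0.10.2 and matplotlib 3.10.9.

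Alternatives planned before the data were examined were median-of-ratios scaling, minimums of 200 and of 10 summed counts, removal of likely doublets, removal of cells over 10% mitochondrial counts, equal weight for every cell, thinning, equal class weights, new clusters, and other UMI minimums and thinning depths for cycling. Alternatives chosen after seeing the data were removal of cells over 60000 UMIs, removal of Conj and Immune cells, Basal or Wing cells alone, and, for the gene lists, equal class weights, thinning and removal of GC and length trends.

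The steps were tested on simulated data drawn from the real means and library sizes, with 200 genes changed. Over the 13846 genes of the all-cell comparison, 48 of 50 genes raised 2-fold, 49 of 50 lowered 2-fold and 50 of 50 raised 3-fold were called, against 5 of 13646 unchanged genes. In the basal class (11862 genes) the same counts were 49, 45 and 50 of 50, against 13 of 11662 unchanged genes. In the suprabasal class (12555 genes) they were 50, 48 and 50 of 50, against 13 of 12355. Apart from the changed genes, both simulated libraries had the same means, with no variation between animals, pools or cells. The few unchanged genes called therefore reflect counting error only. They do not tell how many calls in the real data come from ordinary differences between pools. The ratio intervals held the simulated fold for 94.5% of the changed genes in all cells and 91.5% in the basal class, but for 69.0% in the suprabasal class. There the changed genes included abundant ones that raised the library total by 4.09%, which moves every CPM ratio. Set against the fold after that shift, coverage was 94.5%. A ratio interval therefore leaves out errors of scaling of a few percent, which for abundant genes exceed the counting error.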

Results

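The comparison asked how the corneal epithelium of mice with streptozotocin-induced diabetes differs, cell type by cell type, from that of control mice. The control library held 9605 cells and 196359192 UMIs, with a median of 16487 UMIs per cell. The diabetic library held 8203 cells and 171030636 UMIs, with a median of 17677. The median mitochondrial share was 1.60% in control and 1.67% in diabetic cells. Each group was 1 library made from a pool of animals, so there are no replicates, and every interval below covers counting error only.

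Among the fixed markers of its own layer, each of the authors' labels had leading genes by fold over the other labels. LSC cells were led by Apoe, Gpha2 and Ifitm3, Basal cells by the hemidesmosome genes Itgb4 and Col17a1 with Wnt10a, and TAC1 cells by the DNA replication genes Pcna, Rrm2 and Tyms. TAC2 cells were led by the histone genes Hist1h1b and Hist1h2ap and the mitotic gene Ube2c. Wing cells were led by the desmosome genes Dsg1a and Dsc2 with Lypd3, Squam cells by Psca, Cldn23 and Ndrg1, Conj cells by the keratins Krt19 and Krt4 with Cyp2f2, and Immune cells by the antigen presentation genes Cd74, H2-Ab1 and H2-Eb1. Markers of other lists were raised as well. In TAC1 cells Itgb4 (159 CPM), Col17a1 (1428 CPM) and Wnt10a (109 CPM) were slightly higher than in Basal cells (154, 1336 and 98.4 CPM). These genes therefore do not set Basal cells apart from TAC1 cells. In LSC cells the conjunctival Wfdc18 (111 CPM, 71.9-fold over the other labels), the basal Igfbp2 (347 CPM, 71.5-fold), the stromal Dcn (20.3 CPM, 66.7-fold) and the endothelial Car3 (27.7 CPM, against 0.00832 in the other labels) exceeded the fold of 30.8 for Apoe. Cyp2f2 was at 246 CPM in LSC and 111 CPM in Conj cells, and in Squam cells the neutrophil marker S100a9 had 56.7-fold the level of the other labels. Free RNA was present in both libraries. UMIs of Krt12, the corneal keratin, were found in 100% of control and 80.0% of diabetic Immune cells, at median depths of 2424 and 3044 UMIs. Its level there was 7411 CPM in control and 764 CPM in diabetic cells, and that of Aldh3a1 10023 and 510 CPM, from 26 and 10 cells. Psca, at 28930 CPM in control and 40529 CPM in diabetic Squam cells, was found at 80.0 and 38.5 CPM in Basal cells.

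LSC-labelled cells made up a larger share of the diabetic library, and Wing cells a smaller one. The LSC share was 2.10% in control (202 cells; 95% interval 1.83 to 2.41) and 4.04% in diabetic cells (331 cells; 3.62 to 4.48), a ratio of 1.92 (1.502 to 2.46). Basal cells made up 26.1% and 29.0%, and TAC2 cells 6.84% and 8.61%, with intervals that did not overlap. For TAC1 and TAC2 cells together the shares were 19.97% and 20.96%, a ratio of 1.05 (0.966 to 1.14), and 1.003 without likely doublets. Wing cells made up 30.2% of control and 24.1% of diabetic cells, a ratio of 0.796 (0.743 to 0.854). The shares of TAC1 (13.1% and 12.3%), Squam (16.5% and 16.4%), Conj (4.84% and 5.36%) and Immune cells (0.271% and 0.122%, from 26 and 10 cells) had overlapping intervals. After clustering again without centring, the intervals were apart for TAC1 (ratio 0.876, 0.780 to 0.984) and Conj cells (1.21, 1.035 to 1.43), and with centring both overlapped. Depth differed within TAC2, with a median of 16629 UMIs in control and 24500 in diabetic cells. Shares of dissociated cells also depend on how well each layer came off the tissue, which was not measured here.

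**Figure D1:**
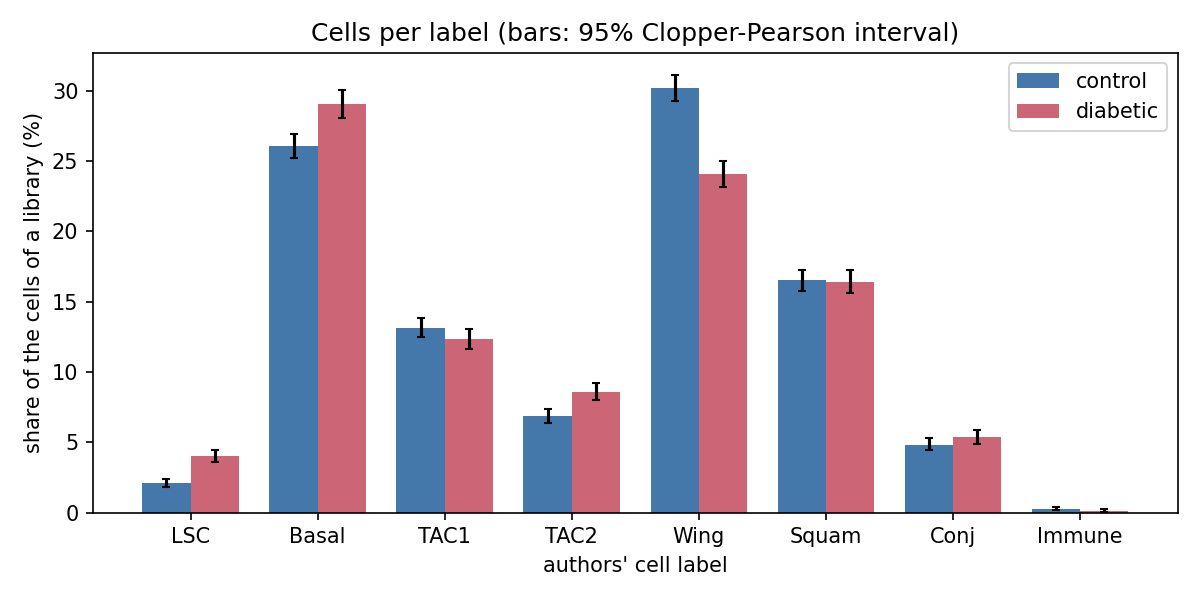
Share of the cells of each library (%) per label of the authors, control and diabetic side by side, with 95% Clopper-Pearson intervals. The LSC bars stand at 2.10% and 4.04% and the Wing bars at 30.2% and 24.1%.

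Over all cells, genes that respond to glucocorticoids and to glucose were among those higher in the diabetic library, and interferon-induced genes were among those lower. Fkbp5, a co-chaperone of the glucocorticoid receptor (chromosome 17, 28399094 to 28517527 on GRCm38), was at 20.3 CPM in control and 68.6 CPM in diabetic cells, 3.38-fold higher (3.26 to 3.50). Txnip, a thioredoxin-binding protein induced by glucose (chromosome 3, 96557957 to 96561883), was 2.05-fold higher (2.02 to 2.08), at 176 and 360 CPM. Isg15, an interferon-induced ubiquitin-like protein (chromosome 4, 156199424 to 156200818), was 2.00-fold lower (1.95 to 2.06), at 93.1 and 46.4 CPM. By the rule of size 828 genes were higher and 387 lower in the diabetic library, of 13846 measured. These counts include differences in cell makeup. With the same class weights in both libraries 556 genes were higher and 360 lower, and 541 of the higher and 326 of the lower calls were kept.

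Among the other named genes, Slc6a6, the taurine transporter (chromosome 6, 91684053 to 91759066), was 2.15-fold higher, and the glucocorticoid-induced Tsc22d3 was 2.02-fold higher. Gpha2 (chromosome 19, 6226380 to 6227768), which encodes a glycoprotein hormone subunit, was 2.18-fold higher over all cells. It was higher in 6 of the 7 epithelial labels but 1.40-fold lower in LSC cells themselves. Cyp2b19, an epoxygenase of keratinocytes, was 3.44-fold higher, and the lipoxygenase Alox12e was 2.80-fold higher. The linker histone gene Hist1h1b (2.23-fold), the immediate early gene Fosb (2.41-fold), the nuclear noncoding RNA Neat1 (1.89-fold) and the keratins Krt14 (1.79-fold) and Krt4 (1.72-fold) were also higher. Hist1h1b was at 641 CPM in TAC2 cells and 7.45 CPM in the other labels, so its fold includes the larger share and depth of diabetic TAC2 cells. It was higher in 6 of 7 epithelial labels. Within labels Krt14 ranged from 1.19-fold lower in Squam cells and 1.205-fold higher in TAC1 to 2.35-fold higher in Conj cells, and with the same class weights in both libraries its log2 ratio over all cells was 0.53, against 0.84. Akr1b7, an aldo-keto reductase (chromosome 6, 34412334 to 34423142), was 2.41-fold lower, and Fgfbp1, a carrier of fibroblast growth factors, was 2.14-fold lower. The membrane serine protease Tmprss11d was 1.94-fold lower. The tubulin gene Tubb2a (1.90-fold), the membrane mucin gene Muc15 (1.86-fold), Adtrp (1.84-fold), Plac8 (1.74-fold), the splicing factor gene Srsf5 (1.69-fold) and the interferon-induced Ifit3 (2.19-fold) and Ifit1bl1 (1.74-fold) were lower. Fkbp5, Txnip, Slc6a6, Tsc22d3, Neat1 and Cyp2b19 were higher by any size in 7 of 7 epithelial labels, and Akr1b7, Fgfbp1, Tmprss11d, Isg15, Tubb2a, Plac8, Adtrp, Muc15, Ifit3 and Srsf5 were lower in 7 of 7. In labels where such a gene is weakly expressed its value includes free RNA, whose part was not measured, and Psca was lower in diabetic Basal cells while higher in diabetic Squam cells. Ifit3 and Ifit3b, Tubb2a, Akr1b7 and the histone genes have close paralogs, so their counts depend on how shared reads were assigned. Scaling by the median of ratios moved the split to 649 higher and 486 lower.

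**Figure D2:**
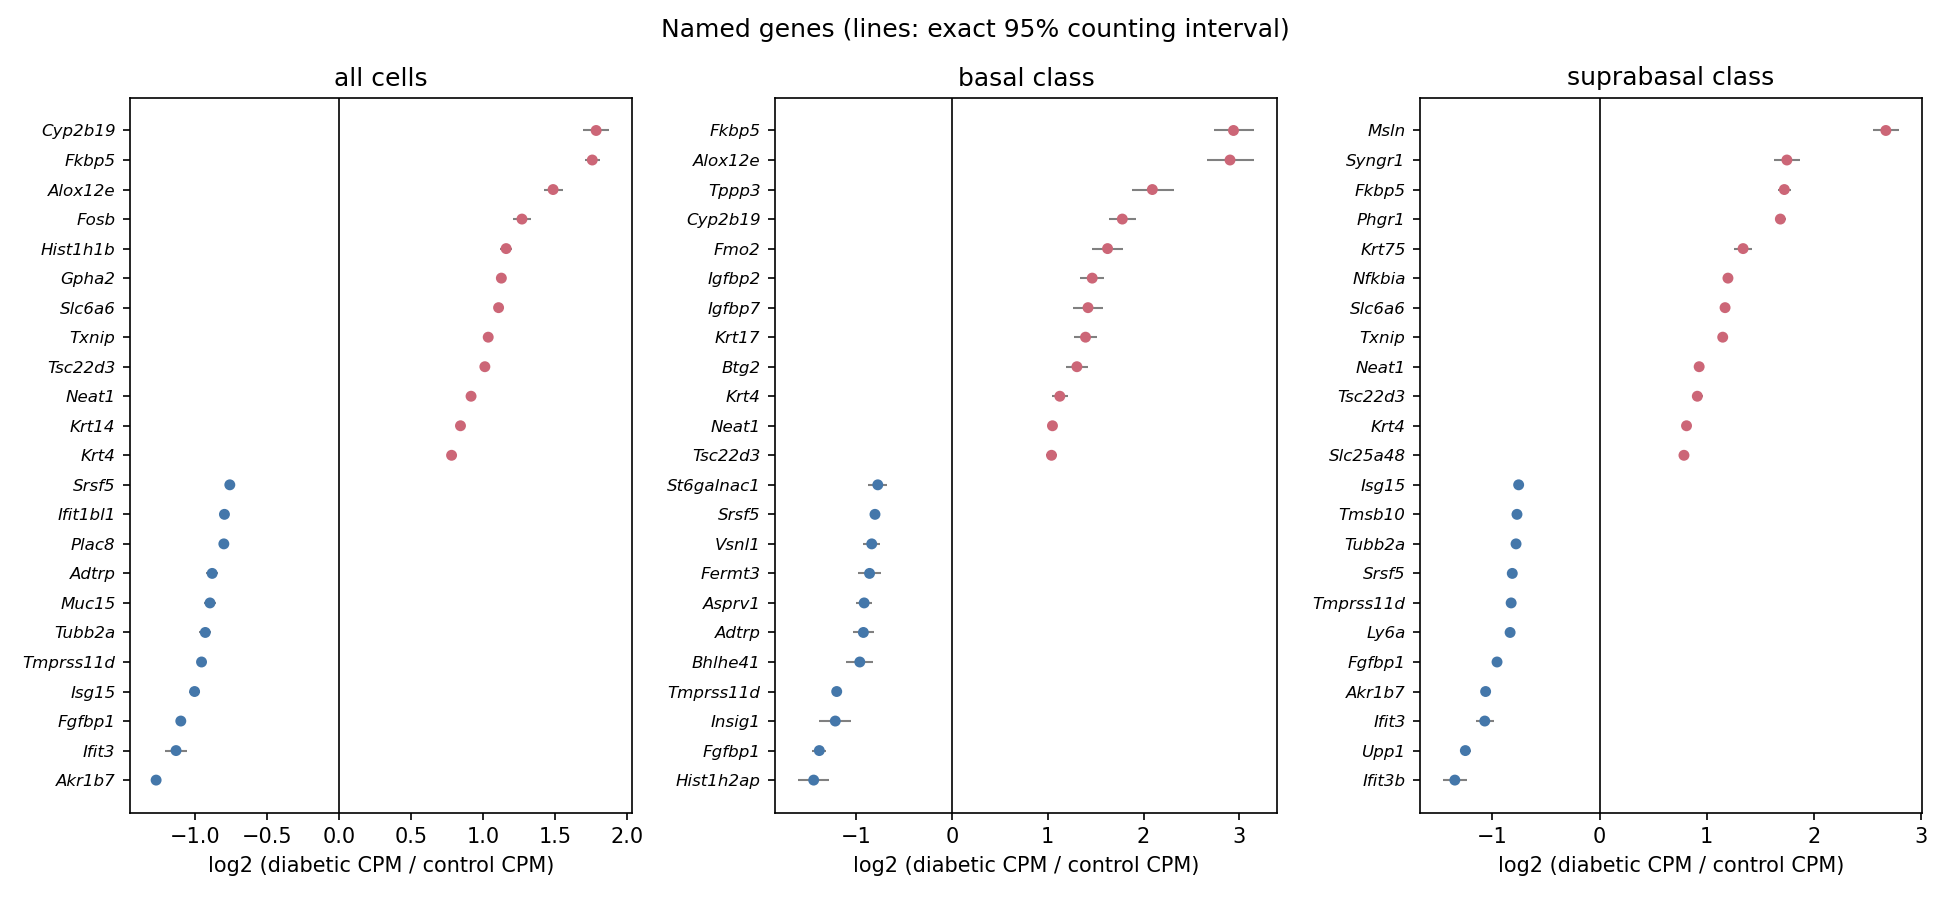
Log2 ratio of diabetic to control CPM for the named genes in all cells, the basal class and the suprabasal class, with exact 95% counting intervals as lines. Fkbp5 lies among the highest in each of the 3 panels.

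Cholesterol synthesis genes were lower in the diabetic library as a group. Their median log2 ratio was -0.53, lower than in all 10000 random lists (percentile 0), and 15 of 15 measured members had a ratio below 1. By the rule of size 3 of them were lower, among them Fdft1, which makes squalene (94.5 and 57.1 CPM, 1.65-fold lower), and Sqle, which oxidizes it (127 and 82.2 CPM, 1.54-fold lower). That count depends on the scaling, and was 8 of 15 under median-of-ratios scaling. The list median was below 0 in 7 of 7 epithelial labels and below the random range in 6, the exception being Conj cells (-0.03).

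Interferon response genes were lower too, with a median of -0.35 (percentile 0) and 6 of 16 members lower by the rule, among them Ifit1 (10.6 and 3.82 CPM, 2.77-fold) and Ifit3. Ifitm3 went the other way, at 33.1 and 54.6 CPM, 1.65-fold higher. It was at 689 CPM in LSC cells, whose share was larger in the diabetic library. In Wing and Squam cells together Ifitm3 was lower, at 9.55 CPM in control and 8.02 CPM in diabetic cells. The interferon list lay below the random range in 6 of 7 labels, and in LSC cells its median was -0.19. The antigen presentation list (MHC class I) had a median of -0.15 (percentile 2.20), with 0 of 9 members past the rule. It lay within the range without likely doublets (percentile 5.79) and with GC and length trends removed (percentile 3.26). Tight junction genes had a median of -0.23 (percentile 0.02), with Cldn3 at 84.0 and 57.2 CPM while Cldn1 was 2.28-fold higher. In the basal class the tight junction median was 0.064. The unfolded protein response list (-0.18, percentile 0.08), the polyol, hexosamine and glycation list (-0.15, percentile 1.29) and the desmosome and adherens junction list (-0.15, percentile 2.21) were also below the random range, each with 0 members past the rule. The desmosome list lay within the range with the same class weights in both libraries (-0.07, percentile 21.6) and after thinning (-0.13, percentile 3.58). In the polyol list, aldose reductase Akr1b3 was at 328 CPM in control and 226 CPM in diabetic cells, and sorbitol dehydrogenase Sord at 35.7 and 44.6 CPM.

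Insulin and glucose response genes were higher as a group, with a median of 0.22 (percentile 99.8) and a median above the random range in 7 of 7 labels. By the rule 4 of 15 members were higher: Txnip and the insulin-like growth factor binding proteins Igfbp2 (5.55 and 17.6 CPM, 3.17-fold), Igfbp5 (44.8 and 67.3 CPM, 1.503-fold) and Igfbp3 (0.0662 and 0.766 CPM, 11.6-fold). Igfbp2 was at 347 CPM in LSC cells, whose share was larger in the diabetic library, and at 4.84 CPM in the other labels. It was higher in 5 of the 6 epithelial labels where it was measured. In Wing and Squam cells together it was at 0.577 CPM in control and 0.670 CPM in diabetic cells. Immediate early genes, which cells also switch on during dissociation, had a median of 0.30 (percentile 100) with 6 of 18 higher, including Nr4a1 (0.239 and 2.03 CPM, 8.50-fold) and Socs3 (0.413 and 2.58 CPM, 6.25-fold). G2 and M phase genes had a median of 0.73 (percentile 100) with 16 of 16 higher, including Mki67 (26.0 and 47.0 CPM, 1.81-fold) and Ccnb2 (9.38 and 17.5 CPM, 1.86-fold). With the same class weights in both libraries that median was 0.42 with 0 of 16 past the rule, and after thinning it was 0.47 with 3 of 16. Within labels the median was above 0 in 5 of 7 and below 0 in Basal (-0.10) and Squam cells (-0.64). S phase genes had a median of 0.23 (percentile 99.9) with 0 of 16 past the rule, and their median was -0.00093 after thinning. Cornified envelope genes had a median of 0.28 (percentile 99.3) with 4 of 13 higher, such as Ly6d (4.27 and 6.999 CPM) and Krtdap (0.153 and 1.76 CPM). Under median-of-ratios scaling 2 of 13 were higher. Hemidesmosome and basement membrane genes had a median of 0.16 (percentile 98.4) with Lamb3, a laminin chain, 1.60-fold higher. That list lay within the random range with the same class weights (percentile 85.8), after thinning (percentile 82.2) and with GC and length trends removed (percentile 89.4). Ribosomal protein genes had a median of 0.13 (percentile 99.98) with 0 of 28 past the rule, and -0.0084 in the basal class.

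The other 19 lists lay within the random range over all cells. Their medians were -0.05 for glycolysis, -0.10 for nuclear oxidative phosphorylation, 0.00 for mitochondrially encoded genes, -0.01 for fatty acid oxidation and PPAR targets, 0.06 for antioxidant genes, 0.13 for metallothioneins and 0.07 for heat shock genes. They were 0.16 for inflammatory mediators, -0.08 for wound repair, 0.02 for corneal epithelial identity, -0.03 for mucins and glycocalyx, 0.04 for Notch, 0.09 for Wnt, and 0.09 for TGF-beta and BMP. They were 0.01 for nerve-derived and guidance cues, 0.11 for the circadian clock, -0.04 for autophagy and lysosome, 0.09 for p53, apoptosis and senescence, and 0.01 for ion and water transport. Single members still passed the rule, such as the chemokine gene Cxcl2 (4.60-fold higher), the wound keratin Krt17 (2.42-fold higher), the glutathione synthesis gene Gclc (1.76-fold higher), the clock gene Arntl (2.02-fold higher) and the cytokine gene Il18 (1.53-fold lower). Inflammatory mediators lay above the random range after thinning (0.37) and with GC and length trends removed (0.24), while with the same class weights their median was -0.01. The nerve-derived cues lay below it after thinning (-0.18). Of the lists outside the range over all cells, those for the polyol pathway, antigen presentation, tight junctions, desmosomes, G2 and M phase and ribosomal proteins lay within it in each class taken alone. The unfolded protein and hemidesmosome lists did so in the basal class, and the cornified envelope and S phase lists in the suprabasal class.

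**Figure D3:**
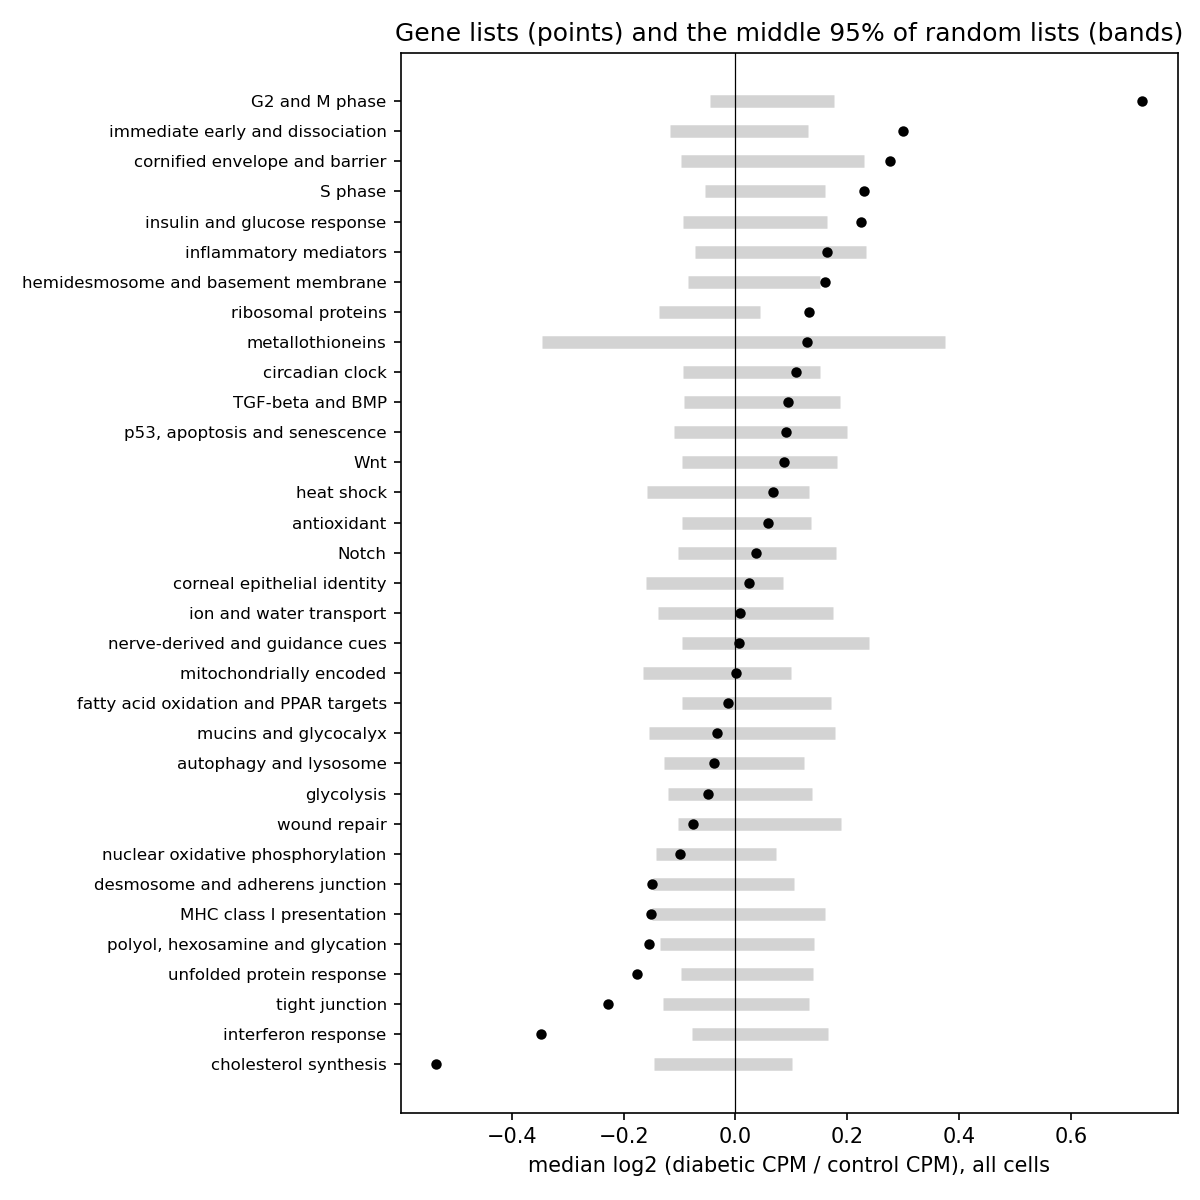
Median log2 ratio of diabetic to control CPM over all cells for the 33 gene lists (points), with the middle 95% of 10000 random lists matched on expression (grey bands). Cholesterol synthesis (-0.53) and interferon response (-0.35) lie furthest below their bands, and G2 and M phase (0.73) furthest above.

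In the basal class, in which 202 of 2707 control and 331 of 2713 diabetic cells were labelled LSC, Fkbp5 was 7.66-fold higher (6.64 to 8.89) in the diabetic library, at 6.16 CPM in control and 47.2 CPM in diabetic cells. Immediate early genes were higher by a median of 0.60, with 9 of 18 past the rule, including Btg2 (2.47-fold). Cholesterol synthesis genes had a median of -0.47, with 7 of 15 lower, including Insig1, which restrains sterol synthesis (2.32-fold), and Fdft1 (1.73-fold). By the rule 444 genes were higher and 205 lower, of 11862. Alox12e (7.47-fold), Cyp2b19 (3.43-fold), the flavin monooxygenase gene Fmo2 (3.08-fold), Igfbp2 (2.76-fold), Igfbp7 (2.68-fold), Neat1 (2.07-fold) and Tsc22d3 (2.06-fold) were higher. Tppp3 (4.26-fold), Krt17 (2.63-fold) and Krt4 (2.18-fold) were higher as well, but in cells labelled Basal alone their log2 ratios were -0.37, -0.26 and -0.077. In those cells Alox12e had 7 and 10 counts, under the minimum, and Igfbp2 was 1.16-fold and Fmo2 2.00-fold higher. In LSC cells Alox12e was at 67.0 and 280 CPM and Igfbp2 at 222 and 406 CPM. Fgfbp1 (2.61-fold), Tmprss11d (2.30-fold), the clock repressor Bhlhe41 (1.95-fold), Adtrp (1.90-fold), Fermt3 (1.81-fold), Vsnl1 (1.79-fold) and Srsf5 (1.74-fold) were lower. Hist1h2ap (2.72-fold), the skin protease gene Asprv1 (1.89-fold) and the sialyltransferase gene St6galnac1 (1.71-fold) were lower too, and these had their highest levels in other labels, at 860 CPM in TAC2, 25388 CPM in Squam and 318 CPM in Squam cells. Insig1 too was highest in Squam cells, at 467 CPM, and Fgfbp1 in Wing cells, at 541 CPM. Inflammatory mediators (0.39), cornified envelope genes (0.57), corneal identity genes (0.05) and the p53 list (-0.17) were outside the random range here, but in Basal cells alone the inflammatory (-0.15) and cornified envelope lists (-0.07) were within it. The tumour suppressor gene Cdkn2a was 5.04-fold lower, at 2.10 and 0.417 CPM.

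In the suprabasal class, Msln, which encodes the surface protein mesothelin (chromosome 17, 25748613 to 25754378), was 6.38-fold higher (5.87 to 6.96) in the diabetic library, at 5.59 and 35.7 CPM. Fkbp5 was 3.31-fold higher, Nfkbia, the inhibitor of NF-kappa-B, 2.30-fold higher and Txnip 2.22-fold higher. In Wing cells alone Nfkbia was 1.26-fold higher (36.6 and 46.1 CPM), against 2.56-fold in Squam cells (153 and 392 CPM). Cholesterol synthesis (-0.47) and interferon genes (-0.33) were lower as lists. By the rule 415 genes were higher and 383 lower, of 12555. Syngr1 (3.36-fold), Phgr1 (3.22-fold), Krt75 (2.53-fold), Slc6a6 (2.25-fold), Neat1 (1.91-fold), Tsc22d3 (1.88-fold), Krt4 (1.76-fold) and the mitochondrial carrier gene Slc25a48 (1.73-fold) were higher. In Wing cells alone the log2 ratio of Slc25a48 was 0.46, and 20 of the genes named for this class moved in size, all in the same direction. Ifit3b (2.55-fold), uridine phosphorylase Upp1 (2.38-fold), Ifit3 (2.10-fold), Akr1b7 (2.09-fold), Fgfbp1 (1.94-fold), Ly6a (1.78-fold), Tmprss11d (1.77-fold), Srsf5 (1.76-fold), Tubb2a (1.72-fold), the actin-binding gene Tmsb10 (1.71-fold) and Isg15 (1.69-fold) were lower. Inflammatory mediators (0.16, percentile 98.3) lay above the random range, with 4 of 14 members higher. Glycolysis (-0.17) and nuclear oxidative phosphorylation (-0.18) lay below the random range here, with Ndufa4 at 1763 CPM in control and 1294 CPM in diabetic cells. Among the labels glycolysis lay below it in Basal (-0.18) and Squam cells (-0.24) but above it in LSC cells (0.25).

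The classes shared more calls than independent lists would. Of 11543 genes measured in both, 132 were higher in both, where lists of those sizes drawn independently would share 10.2, and 84 were lower in both, where they would share 4.49. All counts come from the same pair of pools, so shared calls include whatever differs between the pools as a whole.

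Cells in the G2 and M phases made up a larger share of the diabetic library. After thinning, 10.9% of control cells (10.3 to 11.6) and 13.6% of diabetic cells (12.9 to 14.4) had 2 or more UMIs over the list, a ratio of 1.25 (1.11 to 1.40). Unthinned shares were 18.7% and 22.9%. Within labels, the share was 5.67% and 5.004% in Basal, 20.3% and 19.8% in TAC1 and 1.33% and 2.33% in Conj cells, with overlapping intervals. It was 86.6% and 92.9% in TAC2 and 1.91% and 4.09% in Wing cells, with intervals apart. The shares over these lists were not computed again without likely doublets. Those were 125 of 657 control and 146 of 706 diabetic TAC2 cells, and 307 of 2902 and 179 of 1974 Wing cells. In Squam cells, which have left the cell cycle, it was 1.30% and 0.841%, at median depths of 22382 and 21047 UMIs before thinning. In LSC cells it was 4.14% (1.68 to 8.35) and 9.49% (6.40 to 13.4), and the intervals overlapped. The share with 2 or more UMIs over the S phase list was 32.3% and 33.5%, a ratio of 1.04 (0.976 to 1.10).

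**Figure D4:**
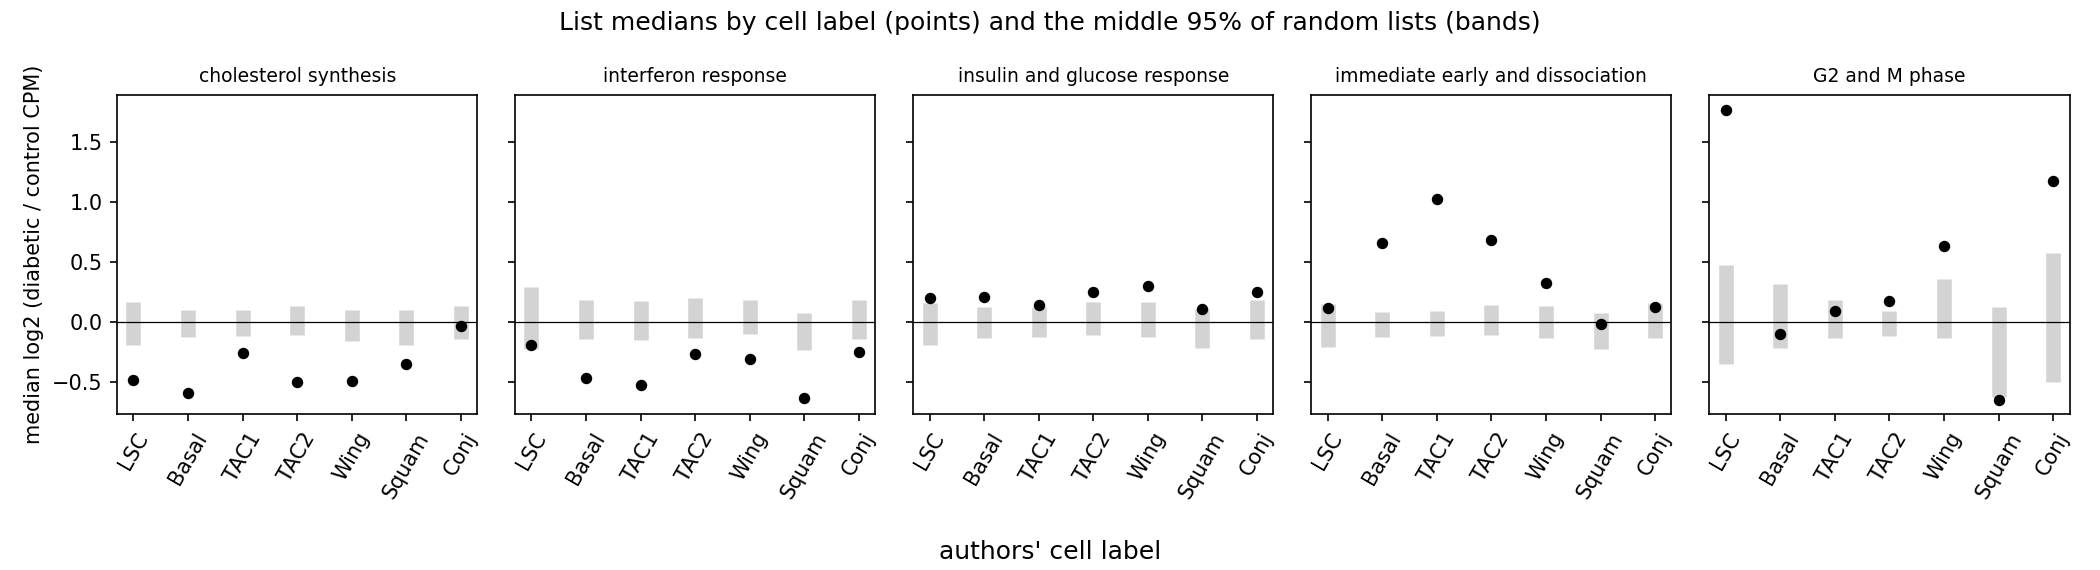
Median log2 ratio of diabetic to control CPM of 5 gene lists in each epithelial label (points), with the middle 95% of random lists (grey bands). The cholesterol synthesis medians are all below 0, from -0.58 in Basal to -0.03 in Conj cells.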

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

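The comparison of directions between the classes was chosen after some of these values had been seen, and with 1 library per group the difference between classes was not tested. Of the 223 genes reported that were measured in both classes, 4 were called in opposite directions. Tppp3 had a log2 ratio of 2.09 in the basal class (6.16 and 26.2 CPM) and -0.70 in the suprabasal class (33.1 and 20.3 CPM), but in Basal cells alone it was -0.37, the same way as in the suprabasal class. Ly6a had 0.62 in the basal class (17.8 and 27.2 CPM) and -0.83 in the suprabasal class (834 and 468 CPM), and in Basal cells alone -0.94. In LSC cells, which the basal class also holds, the log2 ratio was 1.501 for Tppp3 and 0.83 for Ly6a. Areg, which encodes the growth factor amphiregulin, had 1.06 in the basal class (0.710 and 1.49 CPM) and -0.85 in the suprabasal class (20.95 and 11.6 CPM). Lcn2, which encodes lipocalin 2, had 2.32 in the basal class (0.858 and 4.30 CPM) and -0.81 in the suprabasal class (3.16 and 1.81 CPM). In Basal cells alone Areg had 4 and 6 counts and Lcn2 4 and 3 counts, under the minimum of the rule.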

How the results depend on the processing

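No paired analysis was possible because each group has 1 library, from its own pool of animals, and for the same reason no replicate could be left out. Thinning each cell to 5000 UMIs left 400 genes higher and 229 lower over all cells, 290 higher and 149 lower in the basal class, and 208 higher and 281 lower in the suprabasal class (42.5% higher, against 52.0%). Fewer UMIs lower such counts by construction, but thinning also gives cells equal weight and leaves out cells under 5000 UMIs. Of the 828 genes higher over all cells 316 were kept, against 518 with equal weight for every cell and no thinning. A minimum of 200 counts left 247 higher and 118 lower in the basal class, since fewer genes were measured. Over all cells 68.1% of calls were higher, against 57.2% under median-of-ratios scaling. In the basal class 68.4% were higher, against 52.5% in Basal cells alone (303 higher, 274 lower). New clusters made without centring moved the share ratio of LSC cells to 2.52, of Basal cells to 1.23 and of Wing cells to 0.724, put the intervals of TAC1 (0.876) and Conj cells (1.21) apart, which those made with centring did not (0.934 and 1.12), and the cause was not tested. Outside the random range lay 7 lists on each side over all cells, but 3 low in the basal class and 4 high in the suprabasal class. Among genes past the rule of size and lists outside the random range, directions turned for Tppp3 (-0.37), Krt17 (-0.26) and Krt4 (-0.077) in Basal cells alone, which leaves out LSC cells. They turned for tight junction (0.064) and ribosomal proteins (-0.0084) in the basal class and for S phase after thinning (-0.00093), and the cause was not tested. Of the values that answer a comparison, 98 under alternatives stayed within their limits and 11 moved. Of those for single genes and lists, 647 stayed, 200 moved in size and 6 changed sign. A change of sign was counted only for genes past the rule and lists outside the random range in the original setting. Lists within that range changed sign too, such as p53 (0.09, and -0.17 in the basal class) and Notch (0.04, and -0.11 in the basal class and after thinning). Chosen after seeing the data were the alternatives with Basal or Wing cells alone, without cells over 60000 UMIs, without Conj and Immune cells and, for lists, with thinning, equal class weights or GC and length trends removed. With the same class weights 21 of the genes named for all cells moved in size and 3 did not. Depth limits genes with few counts: 12136 were measured over all cells after thinning, against 13846.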

Other observations

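Squam cells showed mostly lower genes in the diabetic library. By the rule of size 185 genes were higher and 799 lower, of 10313 measured, around a median log2 ratio of -0.08 over all genes. Interferon genes had a median of -0.63 there, with 10 of 16 lower. Likely doublets were 155 of 1587 control and 89 of 1347 diabetic Squam cells. The highest UMI total was 155938 in control and 72949 in diabetic Squam cells, and the median genes per cell 3212 and 3036. Psca was at 28930 and 40529 CPM in them, and a rise in an abundant gene lowers the CPM of all others. The Squam counts were not repeated without likely doublets or deep cells, or under another scaling. The part of the other differences in the lower genes was not tested. In LSC cells, G2 and M phase genes had a median of 1.77, with 5 of 7 measured members higher, while 225 genes were higher and 224 lower in all. After thinning, 7 of 169 control and 28 of 295 diabetic LSC cells had 2 or more UMIs over that list, with overlapping intervals. Counting intervals on summed UMIs do not cover the spread between so few cells. In Conj cells 4 members of that list were measured, with a median of 1.18. Wing cells had 475 genes higher and 313 lower, with a G2 and M phase median of 0.63. That median was 0.18 in TAC2 and 0.09 in TAC1 cells, -0.10 in Basal cells, and -0.64 in Squam cells, where it lay below the random range.

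Marker sums of the cell types were close in the libraries for most types. Each sum is weighted to its abundant members, some of which are high in other labels. Krt15 of the limbal list was at 27239 CPM in Conj cells, and Gsto1 of the conjunctival list at 50903 CPM in Squam cells. A ratio near 1 therefore does not show an equal share of cells of that type. The ratio of diabetic to control CPM was 0.988 for the limbal list, 1.05 for basal, 1.15 for cycling, 0.935 for wing, 1.08 for superficial, 0.934 for conjunctival and 1.09 for goblet markers. It was 1.10 for neutrophil, 1.39 for lymphocyte, 1.21 for stromal keratocyte, 0.998 for corneal endothelium, 0.994 for vascular, 1.06 for Schwann or neural, 1.13 for melanocyte and 0.993 for erythroid markers. Markers of dendritic, Langerhans or macrophage cells were at 58.9 CPM in control and 42.3 CPM in diabetic cells, a ratio of 0.718. Lymphocyte markers reached 0.871 and 1.21 CPM, and stromal keratocyte markers 20.4 and 24.7 CPM.

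All tests of explanations below were chosen after the results were seen. The larger LSC share and the higher Gpha2 came with 3 tests. Tissue taken further into the conjunctiva would raise Conj cells about as much as LSC cells. The Conj share ratio was 1.11 (0.924 to 1.33), and 1.21 (1.035 to 1.43) after clustering again without centring, under the lower bound of 1.502 for LSC. LSC cells carry conjunctival markers themselves, such as Wfdc18 (71.9-fold over the other labels) and Cyp2f2 (29.9-fold, against 17.8-fold in Conj cells), so conjunctival cells may sit in that label and the explanation cannot be decided. The boundary of the label moved when cells were clustered again. Without centring 97 control and 209 diabetic cells were LSC, a share ratio of 2.52, and with centring 147 and 267, a ratio of 2.13. These narrower boundaries did not remove the larger share, but its size depends on them. The new clusters took the majority label of the authors and no wider boundary was tried, so an effect of the boundary is not excluded. Free RNA from LSC cells would carry their other genes into Wing and Squam cells, but 19 other genes with 200 CPM or more in LSC cells and at least 10 times their level in Wing and Squam cells had a median ratio of 0.924 there (upper quartile 1.17), against 1.89 (1.81 to 1.98) for Gpha2. That comparison took LSC cells alone as the source. Gpha2 was also higher in diabetic Basal cells (115 and 254 CPM) and TAC1 cells (120 and 268 CPM), and free RNA from these was not tested. A wider expression of Gpha2 and more limbal cells in diabetes may contribute, as a hypothesis, while tissue from further into the conjunctiva stays open for the LSC share. Uneven dissection or cell recovery between the pools and differences between individual mice are untested.

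The lower cholesterol synthesis genes kept a median below the random range with the same class weights in both libraries (-0.47), with every cell thinned to one depth (-0.47) and with GC content and transcript length trends removed (-0.56). These values argue against cell makeup, depth and gene composition as the whole cause. The removed GC and length trend was small (SD 0.048 on the log2 scale). Lower sterol synthesis in diabetic epithelium may be the source, as a hypothesis found in the same data, and a difference between the pools unrelated to diabetes, such as feeding before collection, was not tested.

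Fkbp5 and Tsc22d3, higher in every epithelial label, were weighed against dissociation, free RNA and glucocorticoid signalling. Free RNA from Wing cells is argued against, since Fkbp5 was 8.77 times the control level in Basal cells (7.49 to 10.3) and 2.90 times in Wing cells (2.77 to 3.05). A list of 18 other glucocorticoid-induced genes, written after Fkbp5 and Tsc22d3 were seen and sharing 7 genes with the other lists, lay above the random range in Basal, TAC1, TAC2 and Wing cells, with a lowest median of 0.33, and the immediate early list did so too, also with a lowest median of 0.33. In Basal cells 4 of 15 measured glucocorticoid list members were higher by the rule and 0 lower, while Klf9 (-0.086), Sgk1 (-0.15) and Mt2 (-0.25) had log2 ratios below 0. Dusp1 and Zfp36, among those past the rule there, also belong to the immediate early list, so the lists are not independent. In LSC, Squam and Conj cells both lists lay within the random range, with lowest medians of -0.13 for the glucocorticoid list and -0.013 for the immediate early list, over members that went both ways, so neither explanation can be decided there. Both glucocorticoid signalling and a stronger response to dissociation may therefore contribute. Neither is excluded in any label, and the values do not separate them in Basal, TAC1, TAC2 and Wing cells, where both fit.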
